A study of Mus musculus with 39 samples.

How the data were processed

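Smart-seq3 libraries of 2-cell and 4-cell mouse embryos (FVB/NJ) were taken as deposited. The 9 expression tables hold, per the labels, TPM, made by the authors with StringTie 2.2.1 on genome build mm10 per the submitters' processing notes; the aligner is not given in the sources used here. Each library was scaled to a fixed sum by the authors, and its column sums to 1000000, so the tables keep no read totals. The 106 site lists deposited by the authors, 1 per library, give for each candidate site a score and the counts of edited and covering reads; the site caller is not given in the sources used here. The deposited score was recomputed from the counts as the tail of a beta distribution above an edited share of 0.01 for 100% of 200000 sites checked (tolerance 1e-06). Every deposited site has at least 5 covering reads and at least 1 edited read. The lists hold 2630318 entries at 1411701 positions, of which 930270 lie in a gene.

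Libraries were grouped by the protein, treatment and stage in their names: 17 fusions and the free editor in 6 runs, and 17 knockdowns and 2 scrambled siRNAs in 3 tables. Libraries are written as r and the number in their file (r001, r101, r201), and these numbers repeat between runs and are used here as names, except where the first digit is named. Among 351 pairs of libraries within groups 0 were identical, and the highest correlation was 0.932. One Ybx1 library has a site list and no TPM column, so the Ybx1 comparisons use 5 libraries for sites and 4 for expression. Groups, tests, gene lists, alternatives and the rule for named genes were chosen before the data were examined. The following were added after: the sense share and the 3′ UTR, coding and intron shares, the lists in editing, the base before the edited A, and as alternatives sites with 2 or more edited reads, sites in sense exons, motifs in 3′ UTR sites alone, motifs without each library, each motif in all fusions, the block for gene lists and the comparison of libraries by first digit.

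Expression was fitted with limma 3.58.1 (trend) in R 4.3.3 on log2(TPM + 1), for genes with a mean of 1 TPM or more over the libraries of a table. All groups of a table shared 1 estimate of spread, and each knockdown was set against scrRNA01, each fusion against the free editor, of its table. Tests were two-sided and p-values were adjusted by Benjamini-Hochberg over all genes of a contrast, with a threshold of 0.05. Repeated gene identifiers in a table were summed. Edited sites per gene were fitted in the same way on log2(sites + 1), for genes with a mean of 0.5 sites or more per library; a gene counts as edited more when it passes and is higher. The number of sites moves with the depth of a library, so relative editing, centred on each library's mean over genes, was run as an alternative. Genes whose groups do not overlap are those with all libraries of 1 group above or below all of the other.

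The 21 gene lists were tested with camera at a preset correlation of 0.01, adjusted over all pairs of list and knockdown, and again with an estimated correlation; lists with fewer than 3 tested members were left out, and the targeted gene was taken out of its own list. The lists were 2-cell zygotic burst, maternal oocyte, cleavage and lineage, cytosolic ribosome, mitochondrial ribosome, mitochondrial transcripts, replication histones, p53 targets, integrated stress, interferon response, transcripts sensitive to nonsense-mediated decay, exon junction complex, TREX and mRNA export, CCR4-NOT and decay, spliceosome and hnRNP, ribosome biogenesis, oxidative phosphorylation, cell cycle, cumulus cells, blood and sperm, and heat shock and RNA quality. Targets of a fusion (10 genes or more) were followed under knockdown with camera, and their median was set against 10000 random lists matched on mean expression in 50 bins.

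Numbers of sites, shares and motif shares per library were compared by exact two-sided permutation tests, adjusted over the fusions or, for motifs, over 7 proteins. Sites were placed on GENCODE vM21 genes with bedtools 2.31.1; the annotation shares 54812 of its gene coordinates (99.3%) with the tables. Sites in exons of several genes (8719) or only in bodies of several genes (3514) were left out of counts per gene. The design foresaw motifs only with an mm10 genome sequence. None was at hand, so transcript sequences of the same annotation were used, in which 773248 of the unique sense exonic sites were found, with base A at 100% of them. Positions are counted from 1 on mm10. The other tools were Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

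Named genes were, in every contrast, the targeted or fused gene. For the 5 knockdowns with the most changed genes the 10 highest and 10 lowest past the threshold with no overlap between groups were added, and for all other contrasts the 3 highest and 3 lowest. Members of the lists may be named in any contrast. For edited genes the 10 with the largest difference were named in the 5 fusions with the most, and 3 in the others. Gene models and pseudogenes were counted but not named by this rule, and some edited genes that it names are not reported here. Percentages of edited reads are means over the libraries listing an example site picked from the same lists. They cover sites with an edited read only, and coverage of unlisted sites is unknown. PCR copies are not independent molecules.

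The alternatives were pseudocounts of 0.1 TPM and 0.5 sites, no filter, a mean of 2 sites, quantile scaling, a fit of only 2 groups, both scrambled controls together, a block by the first digit of the library number, sites with covering reads above the median of the table, expression of the gene subtracted, windows of 20 and 200 nt and leaving out each library in turn. The pipeline was tested on simulated data. With changes planted in the table with Carm1 knockdown, 38.8%, 61.2% and 81.8% of genes changed by 1, 2 and 3 on the log2 scale were recovered, with 12 false calls (9.02% of calls). In the editing table with Rps2 the shares were 0%, 41.8% and 83.3%, with 2 false calls (2.35%), so small differences in editing are mostly missed. The permutation test was checked against scipy in 50 of 50 draws (tolerance 1e-06).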

Results

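RNA was read by Smart-seq3, a full-length method primed on poly(A) tails, from FVB/NJ mouse embryos that had been injected as zygotes. The 39 groups of the series fell into 2 experiments. In the editing experiment the embryos received mRNA for rABE, an adenosine deaminase that changes A to inosine in RNA (read as G), either free or fused to 1 of 17 proteins. In the knockdown experiment they received siRNA against 1 of the same 17 genes or a scrambled siRNA, together with histone-GFP mRNA. Embryos were taken at the 4-cell stage (48 h), and for 1 editing run at the 2-cell stage (30 h). The values comprised 194 libraries with TPM in 9 tables and 106 lists of edited sites from 6 editor runs. Groups held 3 to 7 libraries, and each test stayed within 1 table, because each table has its own controls.

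Depth is unknown, as the TPM tables keep no read totals. The lists held 1987 to 173742 sites per library, with a median of 10 to 47 covering reads per site. Covering reads were summed over listed sites and so grow with their number. The lowest sums, 77205 to 1829533, were in the 2025-01 run with Cnot8, Hnrnpa1, Igf2bp1 and Pcbp1, and the highest, 12934482 to 19234060, in the NovaSeq run with Ybx1. The number of genes at 1 TPM or more was 11336 to 16436 in the 105 editor libraries and 9062 to 14450 in the 89 knockdown libraries. P-values measure the spread between these libraries, since the labels do not say whether a library is 1 embryo or a pool.

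The first comparison asked whether each siRNA lowered its target. All 17 targeted genes were below every control library in every knockdown library, and 16 of them fell past the threshold (limma, two-sided, adjusted over all genes tested). Magoh, a core protein of the exon junction complex, fell from 517 ± 54.7 TPM in the scrambled control to 3.68 ± 3.57 TPM (SD, n = 5 and 3), which is 0.713% of the control, with adjusted p = 1.02e-12. Rps3 of the small ribosomal subunit was left at 1.4% (10.7 ± 7.61 against 765 ± 98.8 TPM), Ybx1, a cold shock domain protein that coats mRNA, at 2.92%, the RNA helicase Ddx39a (symbol Ddx39) at 3.65%, the mRNA export adaptor Alyref at 3.98% and the RNA-binding protein Igf2bp1 at 4.50%. Hnrnpa2b1 was left at 5.17%, Pcbp1 at 5.2%, the deadenylase Cnot8 at 5.59%, the mitochondrial ribosomal protein Mrps22 at 5.81%, Elavl1 at 8.83%, Rps2 at 9.82%, the arginine methyltransferase Carm1 at 12%, the histone mRNA binder Slbp at 15%, Hnrnpa1 at 16.8% and Ybx3 at 18%. Rbfox2, a splicing regulator, was at 1.21 ± 1.45 TPM against 8.85 ± 3.3 (13.6%, n = 4 and 5) and did not pass (log2 change -2.34, SE 0.54, limma adjusted p = 0.432).

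Log2 changes of the 16 targets that passed ran from -7.24 (SE 0.36) for Magoh to -2.37 (SE 0.34, adjusted p = 0.00158) for Ybx3. The call on Carm1 (log2 change -2.52, SE 0.42, limma adjusted p = 0.0247) was lost without Carm1 knockdown library r101 (adjusted p = 0.231), r201 (0.0744) or r202 (0.140) and without control library r002 (0.262) or r101 (0.307) of that table. Fitted with only the knockdown and its control, Carm1, Ybx3, Elavl1, Igf2bp1, Ddx39 and Mrps22 kept their log2 change and no longer passed in limma (adjusted p = 0.138 to 0.783).

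**Figure D1:**
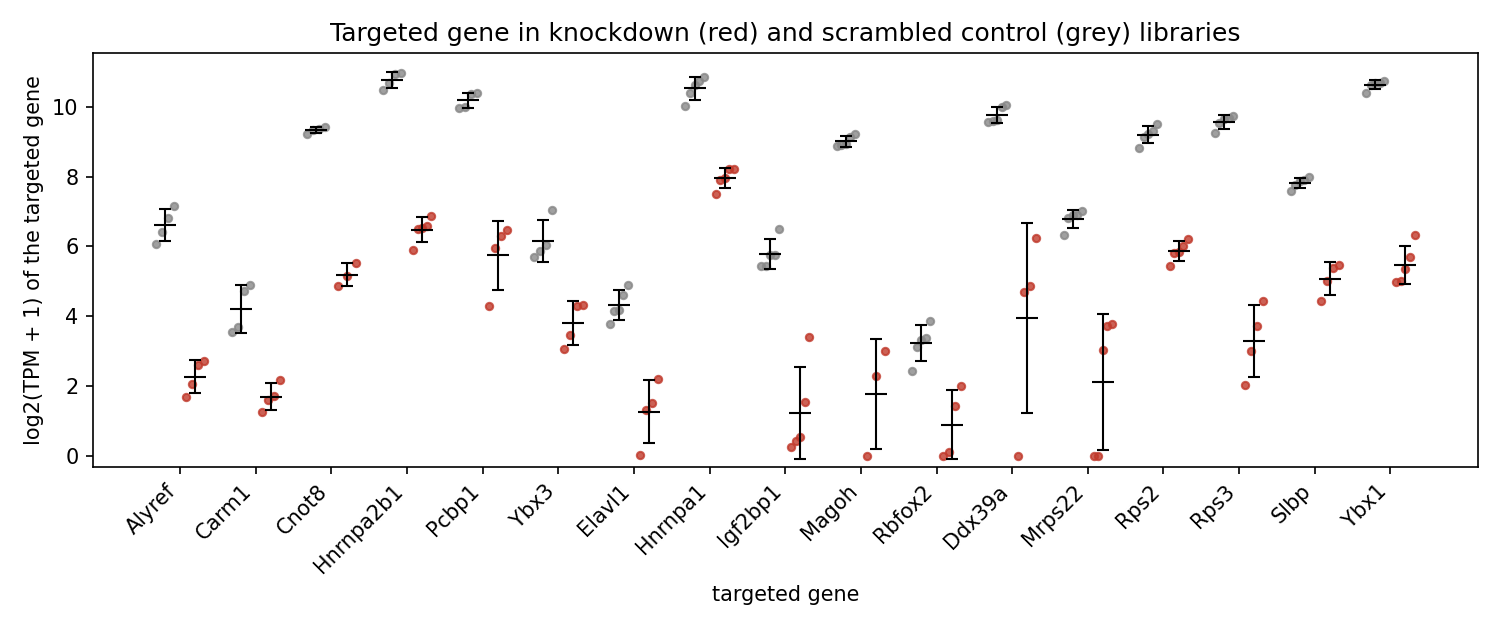
Log2(TPM + 1) of each targeted gene in the scrambled control libraries of its table (grey points) and in its knockdown libraries (red points), with the mean and SD in black. Every red point lies below every grey point of its gene.

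Knockdown of Alyref, which hands spliced mRNA to the export receptor, changed the most genes of the 17 knockdowns. Among the lower ones were H2ax, the histone variant of DNA breaks, at 73.9 ± 33.6 against 440 ± 244 TPM (log2 change -2.51, SE 0.36, adjusted p = 1.53e-04), the lens crystallin Crygs at 0.777 ± 0.928 against 17.4 ± 7.29 TPM, the cold shock protein Csdc2 at 6.99 ± 5.38 against 33.9 ± 5.53 TPM, and Rmi2, a partner of the BLM helicase, at 2.41 ± 1.52 against 14 ± 2.63 TPM (SD, n = 4 and 4). Among the higher ones were Cyb5r1 at 19 ± 6.57 against 2.31 ± 1.62 TPM (log2 change 2.75, SE 0.51, limma adjusted p = 0.00257) and the G-patch protein Gpatch3 at 147 ± 64.9 against 55.1 ± 7.68 TPM (log2 change 1.32, SE 0.21, limma adjusted p = 5.98e-04). Of 14500 genes tested, 32 were higher and 134 lower, against 859 and 774 at an unadjusted p under 0.05. The count was 109 without Alyref knockdown library r002 and 36 when only Alyref and its control were fitted. The calls of 13 other named genes, the higher Tex37, Slc26a11, Fgf5, Stx1a, Shbg, Usp49, C1qtnf12 and Nlrp14 (log2 change 1.29 to 2.97) and the lower Ccdc22, Khk, Ndufaf1, Noto and Cebpa (log2 change -2.65 to -2.04), were each lost without at least 1 single library.

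The other knockdowns changed few genes besides their target. Under Rps3 knockdown the small GTPase Arf1 fell from 112 ± 18 to 12.6 ± 7.76 TPM (log2 change -3.23, SE 0.26, limma adjusted p = 1.41e-09) and Spns1 from 855 ± 109 to 371 ± 62.3 TPM (log2 change -1.21, SE 0.17, limma adjusted p = 3.43e-04, SD, n = 5 and 4). Under Ybx1 knockdown Ccdc59 fell from 77.3 ± 18 to 1.15 ± 1.41 TPM (log2 change -5.41, SE 0.32, limma adjusted p = 1.83e-13, n = 5 and 5), further than Ybx1 itself (-5.15). Off-target action of the siRNAs was not tested. Under Slbp knockdown the serine protease Prss8 was at 13.4 ± 6.14 TPM and listed at 0 in all 5 control libraries (limma adjusted p = 0.0244), a call lost without Slbp knockdown library r001, r002 or r201 or any 1 control library.

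In numbers, 6 genes were lower under Rps3 knockdown, 11 under Rps2 knockdown, 6 under Hnrnpa1 knockdown, 4 under Ybx1 knockdown and 2 under Cnot8 knockdown. 1 was higher and 1 lower under Mrps22 and under Slbp knockdown. For Carm1, Hnrnpa2b1, Pcbp1, Ybx3, Elavl1, Igf2bp1, Magoh and Ddx39a the target alone passed, and for Rbfox2 limma called 0 genes (351 higher and 477 lower at an unadjusted p under 0.05). Of the 11 lower genes of Rps2 knockdown 10 were gene models or pseudogenes, among them Rps2-ps7, Rps2-ps8 and Rps2-ps10, and 5 of the 6 of Hnrnpa1 knockdown were Gm7729, Gm10052, Hnrnpa1l2-ps2, Gm5461 and Gm43097. Copies of a target can take reads from it, so these calls are uncertain, as is that of Ybx1-ps2 under Ybx1 knockdown. The remaining genes, named after their values were seen, were Gm11560 (Ybx1 knockdown), Gm18860 (Cnot8 knockdown), Gm15764 (higher under Mrps22 knockdown) and Gm8130, Gm5823 and Ap4s1 (Rps3 knockdown).

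Single libraries moved these small counts. The count for Rps3 knockdown was 17 without its library r101. That for Rps2 knockdown was 6 without its library r101 or control library r101 and 7 without its library r201 or r202 or control library r001. That for Hnrnpa1 knockdown was 3 without its library r102 or control library r002. The count for Ybx3 knockdown was 3 without its library r201, that for Elavl1 knockdown 3 without its library r001 and 2 without r101, and that for Magoh knockdown 5 without its library r002 and 2 without r101 or r102. Pcbp1 knockdown gave 2 without its library r001 or control library r201, Igf2bp1 knockdown 2 without control library r103, and Rbfox2 knockdown 1 without control library r102 or r103.

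The 2 scrambled siRNAs were compared as a background, in the 1 table that holds both. Between scrRNA02 and scrRNA01 (3 and 4 libraries) limma called 0 genes of 14500, with 849 higher and 516 lower at an unadjusted p under 0.05, where chance gives 362.5 each way. The count was 4 without scrRNA01 library r201, 1 without scrRNA02 library r201 and 6 without scrRNA02 library r202. For gene lists the p-values of this pair were not adjusted. The cytosolic ribosomal protein genes had a median log2 change of -0.21 with scrRNA02 (8 above and 79 below 0, camera p = 8.23e-18 and 0.0532 with an estimated correlation). The mitochondrial ribosomal protein genes were lower (p = 4.06e-06 and 0.00591 with an estimated correlation), as were the nuclear genes of oxidative phosphorylation (p = 7.15e-06 and 0.0145), with medians of -0.12 and -0.13. The genes of the 2-cell burst of zygotic transcription were higher (median 0.55, camera p = 0.00138 and 0.0847 with an estimated correlation), as were the mitochondrial protein transcripts (median 0.39, p = 2.06e-04 and 0.129), and the cleavage and lineage genes were lower (median -0.28, p = 0.0013 and 0.0807). In each of the 8 groups of this table the libraries with a first digit of 2 held on average more genes at 1 TPM (by 584 in the mean) and a higher mitochondrial share of TPM (by 1.09 points) than the others of their group. Such libraries are 1 of 4 for scrRNA01, 2 of 3 for scrRNA02, 3 of 4 for Pcbp1 and 2 of 4 for Alyref and Carm1 knockdown.

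The gene lists fixed beforehand were tested under each knockdown with camera. Of 334 pairs of list and knockdown 44 passed, 24 upward and 20 downward, and with an estimated correlation 0 passed (smallest adjusted p = 0.119), so each list statement below holds at the preset correlation alone. Under Alyref knockdown the nuclear genes of oxidative phosphorylation, which build the respiratory chain, fell as a list: 73 of 93 were below 0 (median log2 change -0.21, adjusted p = 2.02e-10, adjusted p = 0.119 with an estimated correlation). Of them 10 fell and 0 rose over all genes tested, and 18 fell adjusted over the list alone. Limma called Ndufa13 (log2 change -1.12, SE 0.16), Uqcrfs1 (-0.84, SE 0.15) and Cox6a1 (-0.52, SE 0.10). All 12 mitochondrial protein transcripts were above 0 (median 0.39, adjusted p = 5.12e-04, adjusted p = 0.792 with an estimated correlation), of which mt-Nd1, mt-Nd2, mt-Co1, mt-Nd5 and mt-Nd6 rose adjusted over the list alone and 0 over all genes. The mitochondrial ribosomal protein list fell too (56 of 82 below 0, adjusted p = 3.36e-04, adjusted p = 0.663 with an estimated correlation), with Mrpl49 called. Between scrRNA02 and scrRNA01 in the same table these 3 lists moved in the same directions, with medians of -0.13, 0.39 and -0.12, against -0.21, 0.39 and -0.16 under Alyref knockdown.

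The cytosolic ribosomal protein genes fell as a list under 5 knockdowns. They were lower under Mrps22 knockdown (78 of 87 below 0, median log2 change -0.25, adjusted p = 1.39e-18, adjusted p = 0.668 with an estimated correlation), Rps3 knockdown (72 of 86, median -0.19, 1.51e-09 and 0.792), Slbp knockdown (76 of 87, median -0.14, 2.92e-06), Alyref knockdown (67 of 87, median -0.11, 3.56e-06 and 0.942) and Rps2 knockdown (median -0.10, 0.00735). The list rose by a median of 0.06 to 0.08 under Carm1, Hnrnpa2b1 and Magoh knockdown (camera adjusted p = 0.0137 to 0.0419). Members passing adjusted over the list alone were Rpl10l, Rpl35, Rpl27 and Rps27 under Alyref knockdown and Rpl27 under Rps3 knockdown. These shifts are no larger than the median of -0.21 between the 2 scrambled controls, except that under Mrps22 knockdown.

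Lists of the egg and of the zygotic genome moved by larger medians. The oocyte-derived (maternal) genes fell under Ybx3 knockdown (40 of 49 below 0, median log2 change -0.45, adjusted p = 6.52e-06, adjusted p = 0.792 with an estimated correlation), with 0 members past the limma threshold. Plat was at -2.01 and Zar1, which binds maternal mRNA, at -1.57. They rose under Cnot8 knockdown (38 of 49 above 0, median 0.43, adjusted p = 0.00693, adjusted p = 0.947 with an estimated correlation) and under Alyref, Carm1 and Pcbp1 knockdown (0.0379, 0.00968 and 0.026). The 2-cell burst list rose under Carm1 knockdown (21 of 22 above 0, median 0.76, adjusted p = 4.48e-04, adjusted p = 0.668 with an estimated correlation), and under Rps3, Ybx3, Pcbp1, Alyref and Rps2 knockdown (0.00372 to 0.0326). Carm1, Ybx3, Pcbp1 and Alyref share 4 scrRNA01 libraries, against which scrRNA02 had a median of 0.55, and Rps3 and Rps2 share 5 others. Adjusted over the list alone, Usp17lb (log2 change 4.22, SE 1.17) and Tdpoz1 (2.65, SE 0.81) rose under Rps3 knockdown, although members of these families are near-identical copies and their values are uncertain.

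Histone and mitochondrial transcripts gave the remaining larger shifts. The replication-dependent histone genes fell under Mrps22 knockdown (11 of 15 below 0, median -0.50, adjusted p = 0.00262) with H1f5 at -1.47, and under Slbp knockdown (9 of 15 below 0, median -0.57, adjusted p = 0.0399, adjusted p = 0.792 with an estimated correlation), where H1f5 (-1.39, SE 0.41) was the 1 member lower adjusted over the list alone. They rose under Pcbp1 knockdown (13 of 14 above 0, median 1.03, adjusted p = 0.00369, adjusted p = 0.792 with an estimated correlation) and Rbfox2 knockdown (median 0.62, 0.00968), beside a median of 0.79 for scrRNA02 in the table of Pcbp1. Histone mRNA mostly lacks a poly(A) tail, so few are seen here. Mitochondrial protein transcripts were below 0 for 8 of 8 members under Elavl1 (median -0.28, adjusted p = 6.84e-06, adjusted p = 0.668 with an estimated correlation), Hnrnpa1 (median -0.32, 5.40e-06), Igf2bp1 (7.89e-04) and Rbfox2 knockdown (0.00162) and lower under Magoh knockdown too (0.0314), 5 knockdowns that share 1 set of controls. Of these controls, scrRNA01 libraries r001 and r002 held 6.56% and 5.11% of TPM in mitochondrial transcripts, against 3.96% to 4.62% in the other 3, and with an estimated correlation the 5 adjusted p-values were 0.668 to 0.936. They were higher under Mrps22 knockdown (median 0.23, 8 of 8 above 0, 9.82e-05), Carm1 (0.00372), Ybx3 (0.00968) and Rps2 knockdown (0.00164). Of the controls of Mrps22 and Rps2, library r202 held 3.59% against 4.37% to 5.23% in the other 4, and of those of Carm1 and Ybx3, library r002 held 3.36% against 4.28% to 5.17% in the other 3. The median of scrRNA02 against the latter was 0.39.

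The cleavage and lineage genes fell under Pcbp1 knockdown (25 of 34 below 0, median -0.24, against -0.28 for scrRNA02, adjusted p = 0.00162, adjusted p = 0.668 with an estimated correlation) and rose under Elavl1, Hnrnpa1 and Igf2bp1 knockdown (0.0115, 0.0117 and 0.0326). Single calls were those of the spliceosome and hnRNP genes, lower under Cnot8 knockdown (0.0326), ribosome biogenesis genes, lower under Hnrnpa2b1 knockdown (0.0155), transcripts sensitive to nonsense-mediated decay, lower under Mrps22 knockdown (0.0391), mitochondrial ribosomal proteins, higher under Magoh knockdown (0.00966), and oxidative phosphorylation genes, lower under Rps3 knockdown (0.00212). The lists of p53 targets (smallest camera adjusted p = 0.265), integrated stress response (0.184), interferon response (0.250), exon junction complex (0.236), TREX and mRNA export (0.0828), CCR4-NOT and decay (0.316), cell cycle (0.227), heat shock and RNA quality (0.508), cumulus cells (0.620) and blood and sperm (0.691) passed under 0 of the knockdowns.

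The editing experiment asked which RNAs each protein contacts, by the sites that its fusion edits beyond the free editor. The Ybx3 fusion gave the largest excess, at the 2-cell stage, with 133286 ± 33962 sites per library against 10894 ± 2721 (SD, n = 4 and 3). Among the others were the Alyref fusion with 44059 ± 12832 against 15553 ± 4293 (n = 4 and 7), the Hnrnpa1 fusion with 12351 ± 1057 against 4692 ± 1237 (n = 5 and 5) and the Rps2 fusion with 21211 ± 1772 against 12067 ± 3238 (n = 5 and 6). In exact two-sided permutation tests adjusted over the 17 fusions, Alyref (difference 1.5 on the log2 scale, adjusted p = 0.0368), Rps2 (0.85, 0.0368) and Hnrnpa1 (1.44, 0.045) passed. The Elavl1 fusion (42457 against 12067 sites, exact p = 0.0119, adjusted p = 0.0506) and Ybx3 (exact p = 0.0286, adjusted p = 0.0605) did not, and 0.0286 is the smallest exact p that 4 libraries against 3 allow. The Rps2 call was lost (exact permutation, adjusted p = 0.0605) without any 1 of its 5 libraries, with the difference at 0.81 to 0.87. The Mrps22 fusion, with 9028 sites, passed downward without control library r202 (log2 difference -0.45, exact permutation adjusted p = 0.046), and the Slbp fusion, with 8845 sites, without control library r101 (-0.84, 0.0405). The direction for Pcbp1 (-0.09) turned without its library r001 or r101 or control library r101.

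Sites fell on the sense strand of exons to very different degrees, a comparison chosen after the site lists had been seen. In the free editor of the run with Carm1 the sense share was 68.2% ± 6.74 (SD, n = 6). It was higher for the fusions of Elavl1 (92.8%), Alyref (91.3% against 71.9%), Igf2bp1 (92.2% against 74.7%), Ybx3 (98.1% against 86.0%), Hnrnpa2b1 (82.0%), Rps2 (78.9%) and Ybx1 (74.3% against 51.8%). It was lower, and near 50%, for the fusions of Carm1 (48.6% ± 1.14, n = 7), Mrps22 (50.3%), Rps3 (53.2%), Magoh (53.4%), Slbp (48.8%) and Cnot8 (45.1% against 74.7%). These 13 differences passed an exact two-sided permutation test (adjusted p = 0.0092 to 0.0467), and those of Rbfox2, Ddx39a, Hnrnpa1 and Pcbp1 did not (exact permutation, adjusted p = 0.123 to 0.667). At a share near 50% the sites hold about as many antisense as sense positions.

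**Figure D2:**
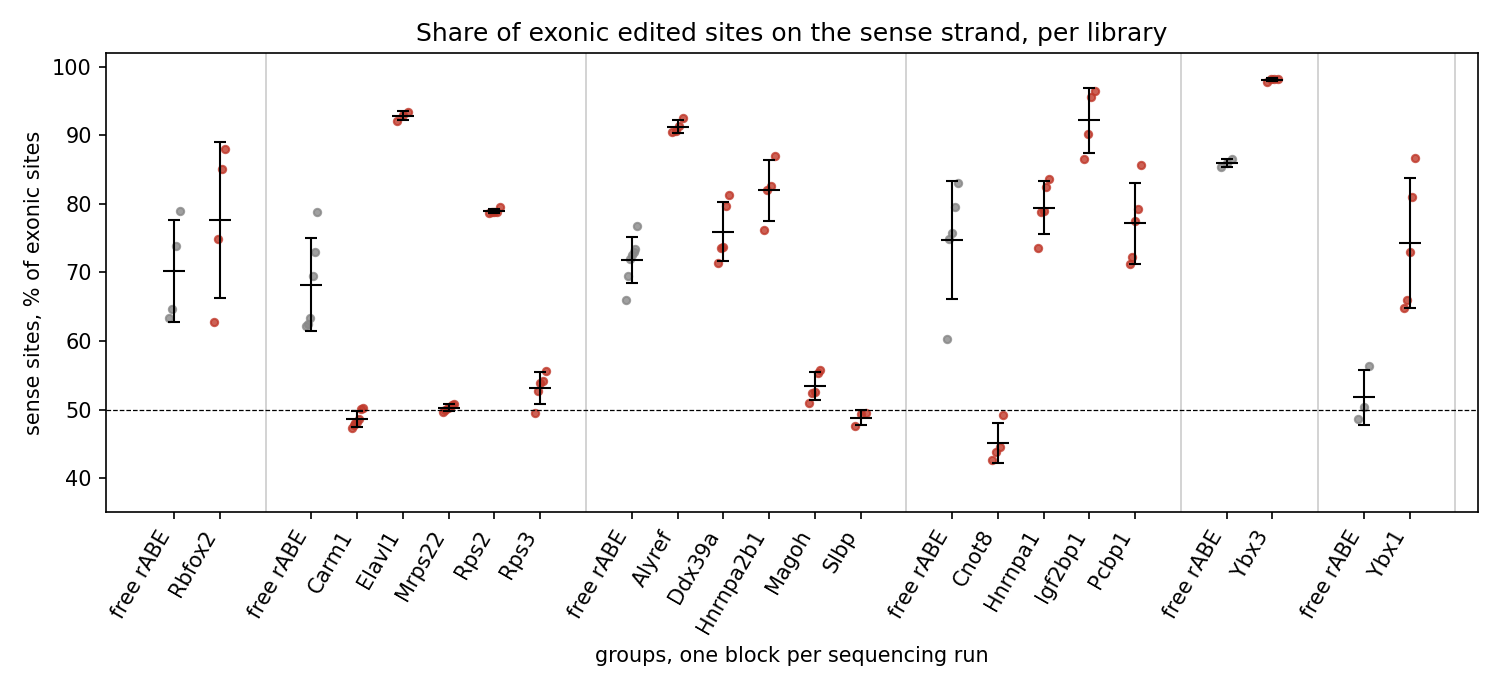
Share of exonic sites that lie on the sense strand of the gene, in percent, for each library (points) of the free editor (grey) and of the fusions (red), in 1 block per run, with the mean and SD in black. The dashed line marks 50%, near which the fusions of Carm1, Mrps22, Rps3, Magoh, Slbp and Cnot8 lie.

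Where on the mRNA the sense sites lay also differed between fusions. Their share in 3′ UTRs was 83.2% for Elavl1, a stabilizer that binds U-rich 3′ UTRs, against 48.1% in the free editor, 71.5% against 50.7% for Rbfox2, 68.7% against 44.5% for Igf2bp1, 58.9% against 40.9% for Hnrnpa2b1, 57.5% for Pcbp1 and 53.6% for Hnrnpa1, both against 44.5%, and 43.4% against 33.3% for Ybx1. For the ribosomal protein Rps2 it was lower, 24.7% against 48.1%, and the coding share was 71.4% against 47.4%. It was lower for Alyref too (35.3% against 40.9%) and for Ybx3 (43.9% against 54.7%). These differences passed an exact two-sided permutation test (adjusted p = 0.00736 to 0.0304). That of Ddx39a (37.3%) did not (exact permutation, adjusted p = 0.0808).

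The Mrps22 fusion edited transcripts of the mitochondrial genome, where the protein is part of the ribosome. Sites on mt-Rnr1, the small ribosomal RNA that Mrps22 assembles on (M:70-1024, mm10), were 28 ± 5.37 per library against 1.83 ± 2.64 in the free editor (SD, n = 6 and 6; log2 difference 3.74, SE 0.44, limma adjusted p = 3.57e-14). On the mRNA of cytochrome oxidase mt-Co1 they were 75.0 ± 11 against 12.7 ± 4.55 (adjusted p = 8.37e-17). They were, on that of cytochrome b, mt-Cytb, 91.0 ± 10.26 against 23 ± 10.5, on mt-Nd1 63.2 ± 9.87 against 11 ± 4.32, on mt-Nd4 21.5 ± 5.86 against 3.00 ± 1.55 and on the large ribosomal RNA mt-Rnr2 72.5 ± 12 against 16.8 ± 6.82. A site in the coding sequence of mt-Co1 (M:6058, + strand) was listed in 6 of 6 fusion libraries with 5.61% ± 1.52 of reads edited (SD, n = 6) and in 1 of 6 controls, with 0.321%. Of the 7 mitochondrial protein transcripts tested 6 were edited more over all genes and 7 adjusted over the list alone, mt-Nd6 passing only there (adjusted p = 0.0547 over all genes). Mt-Nd2 was lost without its fusion library r002 or control library r301. As a list they stood above other genes (median 2.01 against -0.43 for all genes, camera adjusted p = 5.92e-38, and adjusted p = 1.59e-07 with an estimated correlation). Over all fusions 46 of 283 pairs of list and fusion passed, and with an estimated correlation this 1 did. In all, 8 of 2721 genes were edited more and 221 less by this fusion than by the free editor (23 and 55 centred per library). In the other 16 fusions 0 mitochondrial transcripts were edited more, except 1 for Ybx3. That difference between fusions was not tested.

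**Figure D3:**
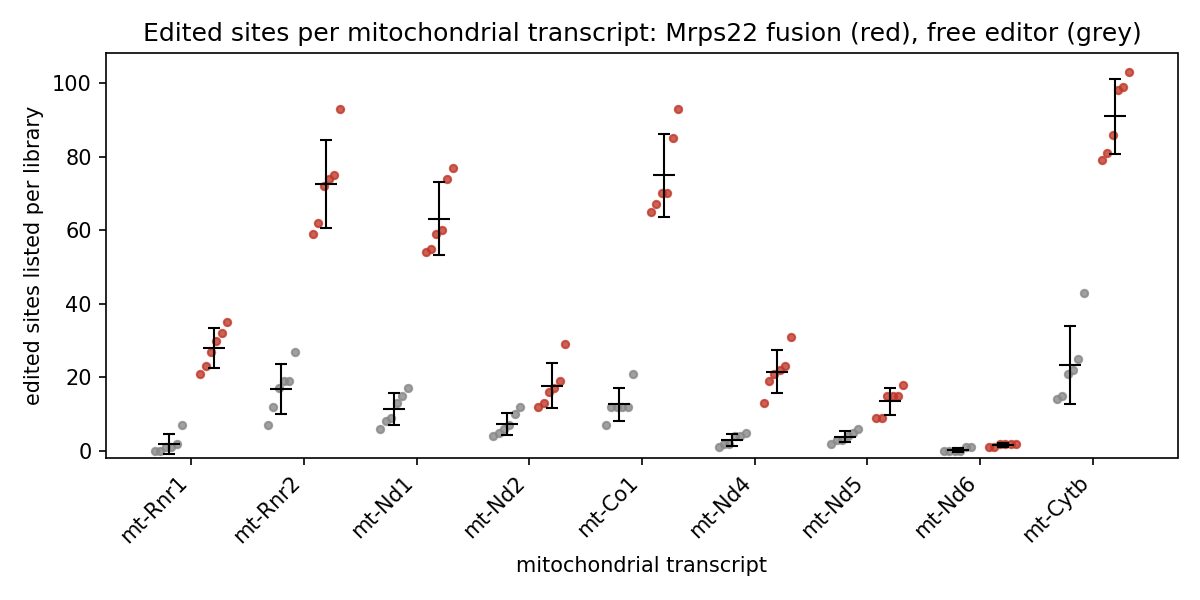
Number of edited sites listed on each mitochondrial transcript in 6 libraries of the Mrps22 fusion (red) and 6 of the free editor of the same run (grey), with the mean and SD in black. The points of mt-Rnr1, mt-Rnr2, mt-Co1, mt-Nd1, mt-Nd4, mt-Nd5 and mt-Cytb lie apart.

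Of 3588 genes the Elavl1 fusion edited 1693 more and 76 less, and 710 more and 766 less when sites were centred per library. Sites on Btg4, an adaptor of maternal mRNA decay (9:51060901-51119875), were 52.0 ± 12.5 against 0.833 ± 1.33 (SD, n = 3 and 6; log2 difference 5.1, SE 0.55, limma adjusted p = 1.17e-10), on the translation inhibitor Pdcd4 33.3 ± 6.35 against a listed 0 (adjusted p = 5.03e-19). They were, on the chaperone gene Dnajb9, 164 ± 63.7 against 5.17 ± 2.32, on Impact 131 ± 22.5 against 4.67 ± 1.97, on the signalling inhibitor Spry2 127 ± 19 against 5.00 ± 2.76 and on Actb 79.7 ± 0.577 against 4.00 ± 4.24. Slc34a2, Efcab14, Inpp4a and Tsc22d2 were next, at log2 differences of 4.58 to 4.84. Sites on Elavl1 itself, where reads of endogenous and injected mRNA were not separated, were 4.33 ± 0.577 against 0.167 ± 0.408 (adjusted p = 1.76e-07). A Btg4 site in the 3′ UTR (9:51119508, + strand) was edited in 27.3% ± 6.76 of reads (SD, n = 3, 8 of 28 reads) and in 0 of 6 control lists. Of 54 cytosolic ribosomal protein genes 4 were higher and 8 lower, and the list stood below the others (adjusted p = 8.81e-08, adjusted p = 0.158 with an estimated correlation).

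Of 4704 genes the Alyref fusion edited 2947 more and 19 less, and 483 more and 568 less when sites were centred per library. Its leading genes were Rsrp1 (21.5 ± 4.80 sites against 0.286 ± 0.488, log2 difference 4.18, SE 0.50, limma adjusted p = 4.18e-11, n = 4 and 7), Fubp1 (43.0 ± 15.9 against 1.86 ± 2.34), Nktr (45.5 ± 14.7 against 1.71 ± 0.756), the centromere protein gene Incenp (49.2 ± 11 against 2.43 ± 1.4), Acin1, Rbm5, the deacetylase gene Sirt7, Prr14l, Ist1 and Slc44a2 (3.69 to 3.91). A site in the coding sequence of Rsrp1 (4:134924348, + strand) was edited in 36.1% ± 10.5 of reads (SD, n = 4, 56 of 152 reads). The ribosome biogenesis list stood above other genes (41 of 45 edited more, adjusted p = 8.64e-05, adjusted p = 0.792 with an estimated correlation) and the maternal list below (1.26e-05 and 0.273). The fusion of Ddx39a, a helicase of the same export pathway, edited 6 genes more and 12 less (19 and 15 centred per library), led by Incenp (18 ± 6.72 against 2.43 ± 1.4, log2 difference 2.58, SE 0.39, limma adjusted p = 4.81e-07, n = 5 and 7), Kri1 and the splicing factor Sf3b2. 3 were higher without Ddx39a library r001 or r302, and without r302 Kri1 and Sf3b2 were lost.

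The Rps2 fusion edited 1010 of 3420 genes more and 17 less, and 131 more and 129 less when sites were centred per library. The adenine nucleotide carrier Slc25a5 held 19 ± 4.85 sites against 2.17 ± 2.14 (SD, n = 5 and 6; log2 difference 2.97, SE 0.45, limma adjusted p = 3.36e-07). The proteasome genes Psmd6 (9.80 ± 2.77 against 0.5 ± 0.837), Psmb6 (10.8 ± 1.92 against 1.17 ± 0.753), Psmd12 and Psmb3, the chaperone gene Pfdn6, the ribosomal scaffold Rack1 (14 ± 4.97 against 1.83 ± 1.6), Zfp622, Fscn1 and Snx5 followed. Of 77 cytosolic ribosomal protein genes 51 were edited more, 57 adjusted over the list alone (median 1.18 against 0.65 for all genes, camera adjusted p = 7.36e-07, adjusted p = 0.25 with an estimated correlation), among them Rps2 itself (log2 difference 1.73, limma adjusted p = 0.00228, endogenous and injected mRNA not separated). The ribosome biogenesis (9.91e-04 and 0.267) and spliceosome lists (0.00104 and 0.385) stood above other genes too.

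In 2-cell embryos the Ybx3 fusion edited 3183 of 4893 genes more and 2 less, and 1119 more and 723 less when sites were centred per library. The largest differences were on Eif2b1, a translation initiation factor subunit (96.8 ± 23.4 sites against 0.667 ± 1.15, log2 difference 6.05, SE 0.48, limma adjusted p = 6.37e-07, n = 4 and 3), Nipsnap2 (103.8 ± 28.7 against 0.667 ± 0.577), the 14-3-3 gene Ywhab (77.8 ± 13.7 against 0.333 ± 0.577), Mkln1, the tRNA synthetase gene Farsb, Dlgap4, Calb1, Myo5b, Auh and Calr4 (5.68 to 5.90). Ybx3 itself held 35 ± 20.9 sites against 1.0 ± 1.0 (limma adjusted p = 5.05e-05), with endogenous and injected mRNA not separated. Of 46 maternal genes 43 were edited more (adjusted p = 1.07e-06, adjusted p = 0.747 with an estimated correlation), and the cell cycle list stood above other genes (0.0234). Its relative, the Ybx1 fusion, was read at the 4-cell stage and edited 254 of 8105 genes more and 0 less (225 and 16 centred per library). These were led by Bard1, a partner of Brca1 (17.8 ± 9.28 against 0.333 ± 0.577, log2 difference 3.74, SE 0.70, limma adjusted p = 5.56e-04, n = 5 and 3), Cdca7l and Unc119b. Ybx1 itself held 102.2 ± 41.5 sites against 33.3 ± 2.08, with endogenous and injected mRNA not separated. The Ybx1 count fell to 0 without Ybx1 library r001, r102 or r103 or control library r001 or r101, to 2 without control library r102 and to 28 without Ybx1 library r101. The calls on these 4 genes were each lost without 5 or more of the 8 single libraries.

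For the Hnrnpa2b1 fusion, 376 of 3675 genes were edited more and 107 less (356 and 195 centred per library), with Khdc1b (67.5 ± 38.3 sites against 4.43 ± 2.15, log2 difference 3.59, SE 0.43, limma adjusted p = 7.79e-12), the nuclear noncoding RNA Malat1 (22.8 ± 2.5 against 1.57 ± 1.27), Arl15 and Hnrnpa2b1 itself (160 ± 42.3 against 19 ± 5.01, endogenous and injected mRNA not separated; SD, n = 4 and 7). The higher count was 220 without its library r101. For Hnrnpa1, 264 of 2444 were edited more and 2 less (132 and 82 centred per library), led by the transcription factor Foxn2 (25.4 ± 9.18 against a listed 0, limma adjusted p = 2.15e-05, n = 5 and 5), Zfp367 (28 ± 10.4 against 0.400 ± 0.548) and the kinase gene Prkd1. The count was 133 without its library r201 and 171, 140 and 122 without control library r001, r201 and r301. The Pcbp1 fusion edited 1 gene more, Hsd17b14 (16.4 ± 4.39 against 0.400 ± 0.548, log2 difference 3.69, SE 0.59, limma adjusted p = 8.50e-05, n = 5 and 5). Its 3′ UTR site at 7:45567248 (+ strand) was edited in 23% ± 4.34 of reads (SD, n = 4 of 5 libraries, 22 of 95 reads). Centred on each library's mean, the Pcbp1 fusion edited 70 genes more and 33 less. The cytosolic ribosomal protein list stood below other genes for Hnrnpa2b1 (6.87e-05 and 0.427 with an estimated correlation) and Hnrnpa1 (7.36e-07 and 0.678).

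The Igf2bp1 fusion edited 1460 of 3247 genes more and 1 less (128 more and 129 less when centred per library), and its 4 libraries were unequal, with 4385, 4833, 66255 and 41995 sites. Tmem50b held 74.8 ± 47.7 sites against 5.60 ± 3.36 (SD, n = 4 and 5; limma adjusted p = 2.42e-05). Cdv3, Klf13, Wsb1, the pluripotency factor gene Sall4, Set, Slc25a4, Psat1 and Taf13 lay at log2 differences of 3.4 to 3.74. The count was 77 without library r401 and 80 without r402 of the fusion, 2397 and 2373 without r201 and r301, and 901 and 848 without control library r201 and r301. Sall4 was lost without r401. The cytosolic ribosomal protein list stood below other genes (3.27e-19 and 0.191 with an estimated correlation).

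For Rbfox2, 35 of 5452 genes were edited more and 0 less (154 and 20 centred per library), led by the oocyte gene Nlrp9c (43.5 ± 33.1 sites against 1.25 ± 1.26, log2 difference 4.11, SE 0.66, limma adjusted p = 5.08e-04, n = 4 and 4), the cell cycle gene Cks2 (46.8 ± 15 against 4.00 ± 4.08) and Paip1, a partner of the poly(A)-binding protein (172 ± 75.1 against 19 ± 17.7). The count was 0 without Rbfox2 library r002, r101 or r102 or control library r003 or r101, 6 and 2 without control library r001 and r002, and 218 without Rbfox2 library r001. The calls on these 3 genes were each lost without 5 or more of the 8 single libraries.

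The other fusions edited genes less, rather than more, than the free editor. Genes edited less numbered 443 for Slbp, 416 for Magoh, 242 for Carm1, 71 for Rps3 and 28 for Cnot8, against 6, 2, 2, 1 and 0 edited more (limma; for Cnot8, 4 genes were higher at an unadjusted p under 0.05). Centred per library, 95 were edited less and 34 more for Slbp, 114 and 52 for Magoh, 45 and 27 for Carm1, 38 and 9 for Rps3 and 22 and 4 for Cnot8. The maternal list stood below other genes for each of them (camera adjusted p = 6.29e-10 for Magoh, 0.118 with an estimated correlation; 6.06e-06 for Carm1, 1.17e-06 for Slbp, 1.07e-06 for Cnot8 and 9.91e-04 for Rps3). Among the genes edited more were Ddah1 (2.67 ± 1.15 sites against 0.286 ± 0.488, n = 3 and 7), Tead1 and Tkfc for Slbp, Noc2l and Pkn3 for Magoh, Usp17lb for Carm1, and Sla2 for Rps3, all at means below 4 sites and each lost without at least 1 single library. The higher count for Slbp was 2 without its library r001. That for Magoh was 4 without its library r302 or control library r301 and 1 without r101. That for Carm1 was 0 without its library r201 or control library r001, 1 without r101 or r202, 4 without r002 and 5 without control library r201. That for Rps3 was 0 without its library r201 or control library r001, r201 or r301, 3 without its library r001 and 2 without r002, r101, r202 or control library r202. That for Cnot8 was 1 without its library r301.

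Known binding motifs were then counted within 50 nt of the sense exonic sites. CCCC lay near 41.7% ± 1.32 of the sites of the Pcbp1 fusion, a protein that binds C-rich RNA, against 22% ± 1.26 in the free editor (SD, n = 5 and 5). TTTTT lay near 34.7% ± 1.44 of the Elavl1 sites against 14.8% ± 0.953 (n = 3 and 6), GCATG near 16.4% ± 1.07 of the Rbfox2 sites against 8.53% ± 0.291 (n = 4 and 4). TAGGG lay near 6.97% ± 0.349 of the Hnrnpa1 sites against 4.02% ± 0.681 (n = 5 and 5) and 7.86% ± 0.267 of the Hnrnpa2b1 sites against 4.35% ± 0.231 (n = 4 and 7). For these 5 proteins the exact two-sided permutation test passed (adjusted p = 0.0185 to 0.0333), and it did so without any single library. For the motif CATC or CACC, Ybx3 sites held 51.7% ± 0.172 against 48.4% ± 1.08 (n = 4 and 3, exact permutation adjusted p = 0.0333). The difference stayed at 2.76 to 3.84 points without any 1 of the 7 libraries, where the smallest exact p possible is 0.0667 or 0.1, so that no call can be made. Ybx1 sites held 56.3% against 55.7% (exact permutation adjusted p = 0.5). Within 20 nt the difference was -0.85 points, and within 200 nt it was 0.64 and passed (0.0357). In 3′ UTR sites alone, a choice made after the data had been seen, it was 2.23 points and passed (exact permutation adjusted p = 0.0357), with 5 of 5 libraries above all controls.

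**Figure D4:**
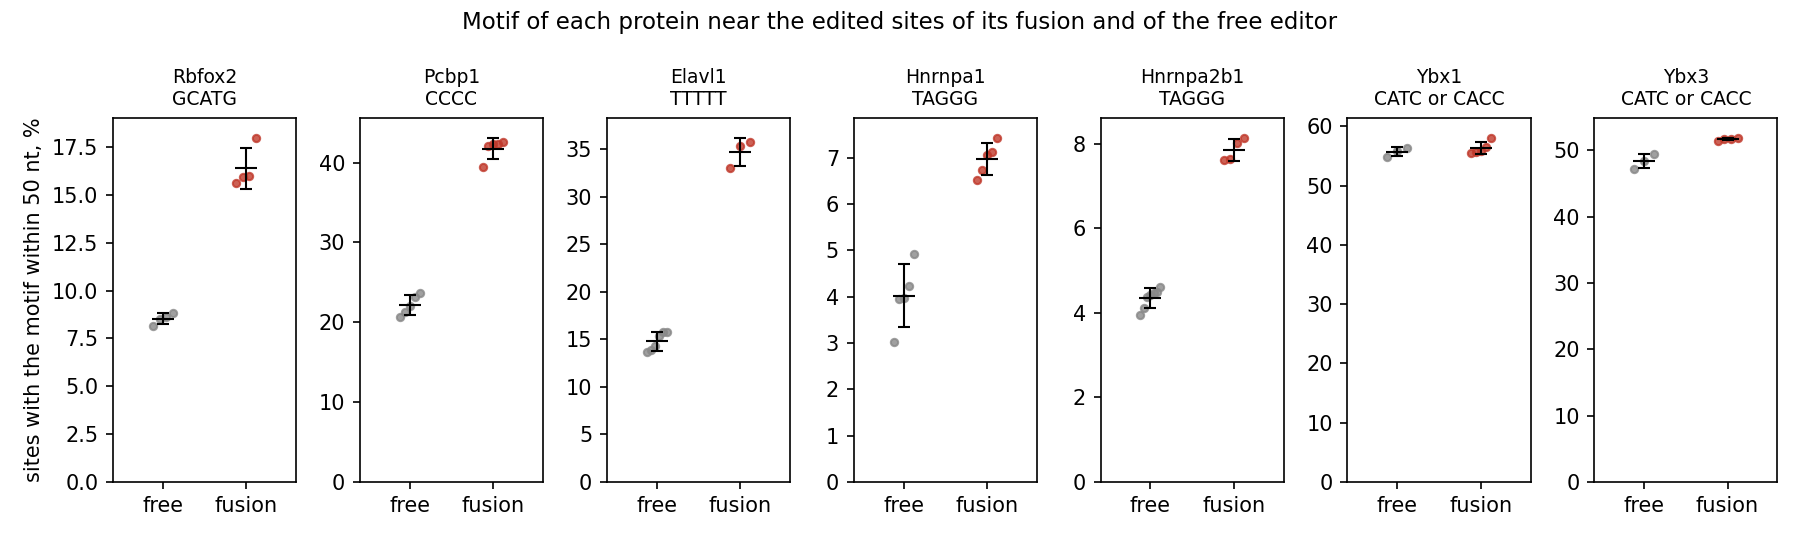
Share of sense exonic sites, in percent, with the motif of the protein within 50 nt, in each library of the free editor (grey) and of the fusion (red), with the mean and SD in black. Red and grey points lie apart for Rbfox2, Pcbp1, Elavl1, Hnrnpa1, Hnrnpa2b1 and Ybx3.

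Transcriptomes of embryos with a fusion were compared with those with the free editor. Ybx3, Alyref, Elavl1 and Hnrnpa1 went with the most changed genes. In Ybx3 embryos (2-cell) the mitochondrial import genes Tomm5 (0.996 ± 1.99 against 105 ± 46.7 TPM, log2 change -6.06, SE 0.62, limma adjusted p = 0.00166) and Timm10 (2.85 ± 3.93 against 103.7 ± 30.7 TPM) fell, as did Rab29 (0.652 ± 1.3 against 43.3 ± 3.48 TPM). Tmed11, Uqcc2 and Cypt1, listed at 0 in the controls, were at 24.3, 17.5 and 12.6 TPM (SD, n = 4 and 3). In Alyref embryos the small nucleolar RNA genes Snora47 (292 ± 356 against 6.79 ± 10.7 TPM) and Snord35a (301.05 ± 187 against 28 ± 23.8 TPM) and the host gene Snhg8 (38.4 ± 5.07 against 4.90 ± 6.33 TPM) rose. In the same embryos Aarsd1 (4.46 ± 3.3 against 87.5 ± 30.2 TPM, log2 change -4.16, SE 0.62, limma adjusted p = 8.51e-05), Reep1 and the tight junction gene Cldn4 (25.3 ± 23.6 against 231 ± 58.6 TPM) fell (n = 4 and 7). Cldn4 fell in Elavl1 embryos too (12.6 ± 14.8 against 190 ± 101.8 TPM, limma adjusted p = 9.64e-04, n = 3 and 6), where Dtd1 and Svbp were listed at 0 against 33.0 and 21.7 TPM and Adhfe1 (32.6 against 0.71 TPM) and Lrrc24 were higher. Usp17lb (595 ± 376 against 50.2 ± 42.6 TPM) was lost without Elavl1 library r001 or r201 or control library r301. In Hnrnpa1 embryos the urokinase receptor gene Plaur rose (107 ± 27 against 16 ± 7.43 TPM, log2 change 2.73, SE 0.28, limma adjusted p = 8.77e-06), as did Shisal2a, listed at 0 in the controls, and mt-Tf and Smco4 fell (n = 5 and 5).

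The counts of changed genes were 370 higher and 1184 lower for Ybx3 (547 and 847 after quantile scaling), 447 and 498 for Alyref (393 and 603), 123 and 340 for Elavl1 and 177 and 69 for Hnrnpa1 (154 and 124). They depended on single libraries. For Ybx3 the total of 1554 was 180 and 391 without control library r101 and r001 and 845, 624 and 562 without Ybx3 library r001, r101 and r103. For Alyref the total was 564 without its library r001, and for Elavl1 233 without its library r001 and 744 without r101. For Hnrnpa1 it was 120, 119, 119, 110 and 120 without its library r201, r202, r301, r302 and r303, and 81, 107 and 112 without control library r001, r101 and r201.

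Smaller sets changed in the other fusions. In Hnrnpa2b1 embryos 7 genes were higher and 49 lower, among them Tmppe (803 ± 106 against 489 ± 79.9 TPM, log2 change 0.72, SE 0.12, limma adjusted p = 0.00574, n = 4 and 7) and Ifitm3, listed at 0 against 24 TPM. The maternal gene Dppa3, at 23216 ± 2627 against 17649 ± 1421 TPM (adjusted p = 0.0248), was not called without its library r101 or control library r303. Quantile scaling cannot test it, since it ranks first in each of these libraries and is given the same value in all. In Ddx39a embryos 6 were higher, with the replication licensing gene Mcm3 at 173 ± 7.71 against 105 ± 16 TPM, and 4 lower, with the sphingosine kinase gene Sphk1 at 4.74 ± 3.91 against 35.6 ± 12.8 TPM (log2 change -2.94, SE 0.45, limma adjusted p = 0.00458, n = 5 and 7). The linker histone gene H1f5 fell in Slbp embryos (44.9 ± 16.9 against 175 ± 33.8 TPM, log2 change -1.99, SE 0.32, limma adjusted p = 0.00616, n = 3 and 7), 1 of 4 lower genes, and in Magoh embryos (67.6 ± 24.9 TPM, limma adjusted p = 0.0425), 1 of 7. The Slbp call was lost without its library r101 or r201, and the Magoh call without its library r101, r301 or r302 or without any 1 of the 7 control libraries. In Igf2bp1 embryos 2 were higher, with Serinc3 at 76.7 ± 23.4 against 24.3 ± 4.16 TPM, and 3 lower, Asl, Smco4 and Foxe1. Mdk (higher) and Dffb changed in Mrps22 embryos, mt-Tf in Rps3 embryos and Shisal2a in Pcbp1 embryos. 1 gene was higher and 1 lower in Ybx1 embryos. Limma called 0 genes for Rbfox2, Carm1, Rps2 and Cnot8 (533 and 491, 394 and 380, 464 and 372, and 454 and 1120 higher and lower at an unadjusted p under 0.05).

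These small sets also moved with single libraries. The Hnrnpa2b1 total of 56 was 27 and 25 without its library r001 and r101, and 35, 34, 32, 27 and 27 without control library r001, r201, r301, r302 and r303. The Ddx39a total of 10 was 27 without its library r101, 3 without r201 or r301, and 6 and 5 without control library r001 and r303. The Magoh count was 0 without its library r101 or r302 or control library r101, r201, r301, r302 or r303, 2 without its library r001 or r301, 3 without control library r001 and 47 without its library r201. The Slbp count was 0 without its library r101, 13 without r201 and 2 without control library r301 or r302. The Igf2bp1 total of 5 was 3, 24, 8 and 8 without its library r201, r301, r401 and r402, 1 without control library r001, 0 without r101, r201 or r301 and 11 without r401. The Mrps22 total of 3 was 0 without its library r001, r002, r101, r301 or r303 or control library r002, r202 or r301, 1 without control library r001 or r101 and 7 without r201. The Rps3 count of 1 was 0 without its library r001, r002, r101 or r201 or control library r002, r101 or r202, 2 without control library r001 and 3 without r201. The Ybx1 total was 1 without its library r102, r103 or r104 or control library r001 or r101, the Pcbp1 count 3 without its library r001 or control library r301. That of Carm1 was 1 and 3 without control library r001 and r201, that of Rps2 4 without control library r201, that of Rbfox2 1 without its library r002, and that of Cnot8 1 without its library r101 or r201 and 2 without control library r301.

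The fused gene itself was higher in Elavl1 embryos (84.3 ± 8.45 against 19 ± 6.92 TPM, log2 change 2.15, SE 0.35, limma adjusted p = 4.75e-04), in Alyref embryos (91.1 ± 26.9 against 48.4 ± 6.57 TPM, limma adjusted p = 0.0111) and in Ddx39a embryos (1524 ± 233 against 1014 ± 162 TPM, limma adjusted p = 0.0199). The Alyref call was lost without its library r001 or r201 and the Ddx39 call without library r001, r201 or r301. Carm1 was at 86.2 ± 69.1 against 12 TPM (limma adjusted p = 0.461). The injected fusion mRNA carries the same coding sequence, and its reads were not separated from those of the endogenous mRNA.

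Edited genes of 9 proteins (at least 10 each) were followed under knockdown of the same protein. No set passed camera (adjusted p of 0.202 or more). The 2934 genes edited more by the Alyref fusion had a median log2 change of 0.08 under Alyref knockdown, with 13 higher and 38 lower, and the 1666 of Elavl1 a median of 0.07 under Elavl1 knockdown, at percentiles 100 and 99.97 of 10000 random lists matched on expression. The 372 genes of Hnrnpa2b1 had a median of -0.06, at percentile 0.87 of such lists, the 35 of Rbfox2 one of -0.10, at percentile 11.74, and those of Igf2bp1 and Ybx3 medians of 0.02 and -0.02, at percentile 0. Those of Rps2, Hnrnpa1 and Ybx1 had medians of 0, 0.02 and -0.04, at percentiles 74.11, 49.51 and 49.36. The Ybx3 fusion was read in 2-cell and its knockdown in 4-cell embryos. With targets from editing centred per library, only the 70 of Pcbp1 passed camera (down, adjusted p = 4.42e-04, 0.42 with an estimated correlation). Their median (-0.0599, percentile 2.63) was inside the random range (-0.0603 to 0.0267).

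The free-editor embryos of both stages with the same date show how far the transcriptome moves between 30 h and 48 h. They stand in separate tables, so no test was run. Genes of the 2-cell burst were lower at the 4-cell stage, 30 of 34 of them, with a median log2 difference of -4.30 against -0.42 for all 19672 genes: Zscan4d was at 236 TPM at the 2-cell and 3.46 TPM at the 4-cell stage, and Zfp352 at 331 and 4.92 TPM. Of 51 maternal genes 49 were lower (median -2.95), with the oocyte growth factor genes Bmp15 at 539 and 9.45 TPM and Gdf9 at 739 and 144 TPM, and Btg4 at 6191 and 111 TPM. Of 87 cytosolic ribosomal protein genes 85 were higher (median 2.48), as Rplp0 at 354 and 1972 TPM, and 75 of 82 mitochondrial ribosomal protein genes (1.89), 81 of 95 oxidative phosphorylation genes (1.62) and 39 of 45 ribosome biogenesis genes (1.3). The CCR4-NOT list had a median of -1.71, the mitochondrial transcripts 0.25 and the cleavage and lineage genes -0.15. Of 14 heat shock and RNA quality genes 12 were lower (median -0.86), and the 3 blood and sperm genes had a median of 2.61. Means are over 3 and 5 libraries.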

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

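The tests weighed for the 3 patterns below were chosen only after the patterns had been seen; the search for libraries far from the others of their group was planned.

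Of 165 groups of values examined for 1 library far from the rest, 9 held one, where chance gives about 8.2. Rps2 fusion library r201 had a sense share of 79.5%, against 78.7% to 78.9% in the others. Free-editor library r301 of the 2025-01 run had 35.6% of its sense sites in 3′ UTRs, against 44.8% to 48.4%. Sites edited in all reads numbered 59 in Mrps22 fusion library r001, against 36 to 44, and 1665 in Ybx1 fusion library r001, the 1 without a TPM column, against 270 to 443. Pcbp1 knockdown library r001 had 13621 genes at 1 TPM or more, against 14242 to 14365. The mitochondrial share of TPM was 4.95% in Alyref fusion library r301 (5.41% to 5.46% in the others), 5.05% in Igf2bp1 knockdown library r102 (3.37% to 3.83%) and 6.21% in Rps2 knockdown library r201 (4.82% to 5.06%). Igf2bp1 itself was at 9.62 TPM in Igf2bp1 knockdown library r001, against 0.204 to 1.94 TPM.

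The first pattern is the sense share near 50% in the fusions of Carm1, Cnot8, Magoh, Mrps22, Rps3 and Slbp. Lower depth and lower coverage are argued against: the log2 ratio of antisense sites, fusion over free editor, had a median of 0.16 over the 6 fusions, and the median covering reads per site was higher by 0.933 reads. A candidate explanation is that these fusions edit little, which leaves background entries on both strands: the share of sites with T before the edited A differed from that in the free editor by a median of -19.6 points, with every fusion library below every free-editor library of its run. The Ybx3 fusion, with the most sites of all, was lower too (40.9% against 49.5%), so a lower share alone does not show little editing, and a cause in the amount, activity or place of the fusion protein was not tested.

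The second pattern is the spread of the Igf2bp1 fusion, with 66255 and 41995 sites in libraries r401 and r402 and 4385 and 4833 in r201 and r301, a difference of 3.52 in the mean of log2 sites. A batch shared by all libraries with a first digit of 4 cannot be told apart, since the 1 other such library, of the free editor, had 5745 sites against a mean of 4429, a difference of 0.42 in the mean of log2 sites. Depth may account for part of the spread, because antisense sites differed by 2.11 on the same scale. No biological explanation was tested.

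The third pattern is the lower level of cytosolic ribosomal protein genes under 5 knockdowns (Alyref, Mrps22, Rps2, Rps3 and Slbp); it was higher under 3 others (Carm1, Hnrnpa2b1 and Magoh). A difference among scrambled control embryos is a candidate explanation, as the same list had a median log2 change of -0.21 between scrRNA02 and scrRNA01, larger than the -0.11 under Alyref knockdown in the same table. The Mrps22, Rps2, Rps3 and Slbp knockdowns stand in a table with scrRNA01 alone, where this could not be measured. A loss of ribosomal protein mRNA through these proteins stays open.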

How the results depend on the processing

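Sites with 2 or more edited reads, sites in sense exons, 3′ UTR motifs, motifs without each library and the block for gene lists were chosen only after the data had been seen. All other alternatives were planned, and the cause was not tested except where fewer libraries, genes or sites explain a lower number. The 17 targeted genes kept their direction under every setting run. Depth, which may limit site counts, is unknown.

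Without a filter the changed genes numbered 0 for the Mrps22, Rps3, Magoh, Igf2bp1 and Pcbp1 fusions, 5 for Ddx39a, 32 for Hnrnpa2b1, 11 for Slbp, 117 for Hnrnpa1, 479 for Ybx3 and 1 for Ybx1, and under knockdown 6 for Cnot8, 3 for scrRNA02, 2 for Elavl1 and Igf2bp1, 3 for Magoh, 1 for Rbfox2 and 4 for Ddx39a and Mrps22; the Carm1 target stayed at -2.52 (adjusted p = 0.0578), and genes edited more were 0 for Carm1 and Rps3, 7 for Magoh and 155 for Hnrnpa1. With a pseudocount of 0.1 they were 1 for the Rps2 fusion and 2, 2, 23 and 1 for Hnrnpa2b1, Magoh, Rps2 and Slbp knockdown; with 0.5 sites 4 for Carm1 and 3 for Pcbp1. Quantile scaling gave 1 and 8 for the Rbfox2 and Igf2bp1 fusions and 3, 1 and 6 for Hnrnpa1, Rbfox2 and Rps2 knockdown. With only 2 groups fitted, and so fewer libraries behind the spread, they were 36 for Alyref, 0 for Carm1, Ybx3, Igf2bp1 and Mrps22, 1 for scrRNA02, 4 for Ddx39a and 6 for Rps2 knockdown, and the targets Carm1 (-2.52), Ybx3 (-2.37), Elavl1 (-3.06), Igf2bp1 (-4.53), Ddx39 (-5.81) and Mrps22 (-4.68) no longer passed. Both scrambled controls together gave 2 for Hnrnpa2b1 and Pcbp1 knockdown.

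For genes edited more, a mean of 2 sites gave 69 for Rbfox2, 0 for Rps3, 10 for Ddx39a, 1 for Magoh and Slbp and 11 for Pcbp1. Centred per library the numbers were 154 for Rbfox2, 27 for Carm1, 710 for Elavl1, 23 for Mrps22, 131 for Rps2, 9 for Rps3, 483 for Alyref, 19 for Ddx39a, 52 for Magoh, 34 for Slbp, 4 for Cnot8, 132 for Hnrnpa1, 128 for Igf2bp1, 70 for Pcbp1 and 1119 for Ybx3. Sites with covering reads above the median gave 427 for Elavl1, 582 for Rps2, 875 for Alyref, 1 for Ddx39a and Slbp, 84 for Hnrnpa2b1, 467 for Igf2bp1, 1048 for Ybx3 and 10 for Ybx1. Sites with 2 or more edited reads gave 9 for Rbfox2, 493 for Rps2, 1572 for Alyref, 93 for Hnrnpa1, 13 for Pcbp1, 2075 for Ybx3, 148 for Ybx1 and 1 for Carm1, Ddx39a, Magoh and Slbp. With expression subtracted they were 63 for Rbfox2, 13 for Ybx1, 0 for Rps3 and 1 for Carm1, Ddx39a, Slbp and Cnot8.

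Differences in sites per library (log2) with covering reads above the median were 0.96 for Rps2, 1.22 for Alyref and 1.66 for Hnrnpa1, and none of them passed any more (exact permutation, adjusted p = 0.0506 each). With 2 or more edited reads they passed at -0.96 for Carm1, 3.34 for Elavl1, -0.75 for Mrps22, -0.84 for Magoh, -1.30 for Slbp, 2.61 for Igf2bp1 and 4.71 for Ybx3, and Pcbp1 turned to 0.21. In sense exons they passed at -0.99 for Carm1, 2.15 for Elavl1, -0.92 for Mrps22, -0.66 for Rps3, -1.04 for Magoh, -1.44 for Slbp, -1.94 for Cnot8 and 3.95 for Ybx3. The Ybx1 motif differed by -0.85 within 20 nt, by 0.64 within 200 nt and by 2.23 points in 3′ UTRs, and the last 2 passed (exact permutation, adjusted p = 0.0357 each). With an estimated correlation 0 lists passed under knockdown.

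The replicate block rests on the first digit of the library number. Residuals of libraries that share a digit had a mean correlation of -0.00 to 0.04, above 0.1 in 0% to 5.13% of pairs. In the table with Alyref knockdown libraries with a first digit of 2 still differed, as given above. The groups hold unequal parts of them, so list shifts in that table are partly confounded with the digit. With the block, a test of the lists chosen after the data had been seen, 38 of the 44 pairs of list and knockdown passed. Those lost were the maternal list for Carm1 (adjusted p = 0.13) and Pcbp1 (0.331), histones for Pcbp1 (0.099, median 0.52) and Slbp (0.0716), cytosolic ribosomal proteins for Magoh (0.0744) and decay-sensitive transcripts for Mrps22 (0.099). With the block the changed genes were 0 for Mrps22, 13 for Hnrnpa2b1, 4 for Cnot8, 419 for Hnrnpa1 and 1 for the Igf2bp1 and Ybx1 fusions, and genes edited more 1 for Cnot8, 1139 for Hnrnpa1, 232 for Igf2bp1, 51 for Pcbp1 and 92 for Ybx1.

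Leaving out 1 library at a time, changed genes ranged over 0 to 1 for the Rbfox2 fusion, 0 to 3 for Carm1 and Rps3, 233 to 744 for Elavl1, 0 to 7 for Mrps22, 0 to 4 for Rps2, 564 to 890 for Alyref, 3 to 27 for Ddx39a, 25 to 58 for Hnrnpa2b1, 0 to 47 for Magoh, 0 to 13 for Slbp, 0 to 2 for Cnot8, 81 to 271 for Hnrnpa1, 0 to 24 for Igf2bp1, 1 to 3 for Pcbp1 and Ybx1 and 180 to 1396 for Ybx3. Under knockdown they were 109 to 190 for Alyref, 0 to 1 for Carm1 and Rbfox2, 0 to 6 for scrRNA02, 1 to 2 for Pcbp1, Igf2bp1 and Slbp, 1 to 3 for Ybx3 and Elavl1, 3 to 6 for Hnrnpa1, 1 to 5 for Magoh, 6 to 12 for Rps2 and 5 to 17 for Rps3, with the Carm1 target at -2.75 to -2.30. Genes edited more were 0 to 218 for Rbfox2, 0 to 5 for Carm1, 0 to 3 for Rps3, 3 to 8 for Ddx39a, 220 to 421 for Hnrnpa2b1, 1 to 4 for Magoh, 2 to 6 for Slbp, 0 to 1 for Cnot8, 122 to 238 for Hnrnpa1, 77 to 2397 for Igf2bp1 and 0 to 252 for Ybx1. Differences in sites were -0.45 to -0.27 for Mrps22, 0.78 to 0.97 for Rps2, -0.85 to -0.68 for Slbp and -0.22 to 0.0111 for Pcbp1, and the Ybx3 motif 2.76 to 3.84 points.

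Near 0, some signs turned. The ranges without 1 library were, as log2 changes, -0.02 to 0.13 (fused gene: Rps3 fusion), -0.0343 to 0.0949 (fused gene: Magoh fusion), -0.0302 to 0.17 (fused gene: Slbp fusion) and -0.006 to 0.12, with -5e-04 without its library r303 (fused gene: Hnrnpa1 fusion). After quantile scaling Magoh was at -9e-04. Dppa3 was at 0, a value set by the scaling, since it ranks first in each library of both groups. Edited sites were -0.45 for Rbfox2, -1.13 for Usp17lb and -0.0097 for Magoh with expression subtracted, -0.32 for Alyref and 0.16 for Slbp centred, -0.131 to 0.265 for Magoh without 1 library (below 0 at -0.111 without either of 2 control libraries), and 0 and 0.2 for Pcbp1 with covering reads above the median and with 2 or more edited reads.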

Other observations

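The tests on the base before the edited A, on motifs in all fusions and on splits with genes in either direction were chosen only after the counts had been seen, as was the reading of the other splits.

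The share of sense exonic sites with T before the edited A was, for the free editor, 37.5% ± 4.01 in the run with Elavl1 (SD, n = 6) and 49.5% ± 1.0 in 2-cell embryos (n = 3). It was at a similar level or higher for Igf2bp1 with 49.6% ± 2.13 (n = 4), Elavl1 with 45.4% ± 0.806 (n = 3), Hnrnpa2b1 with 43.9% ± 2.11 (n = 4) and Alyref with 43.2% ± 0.604 (n = 4). It was 16.8% ± 0.785 for Carm1 (n = 7), 19% for Mrps22, 20.7% for Rps3, 18.6% for Magoh, 13.4% for Slbp and 13% for Cnot8. The Ybx3 fusion, in 2-cell embryos, had 40.9% ± 1.01 (n = 4), every library below its free editor. The Ybx1 fusion had 39.0% ± 0.825 (n = 5) against 30.08% ± 1.98 in its free editor (n = 3).

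TTTTT, the motif set down for Elavl1, was also more frequent near the sites of other fusions than near those of the free editor: 24% against 16% for Rbfox2, 21% against 13.7% for Igf2bp1, 17.7% against 11.6% for Hnrnpa2b1 and 17.4% against 13.7% for Hnrnpa1 (exact permutation, adjusted p = 0.00859 to 0.0347). CCCC, set down for Pcbp1, was also more frequent for Slbp (27.7% against 24.8%, adjusted p = 0.0157), Magoh (27% against 24.8%, 0.0147), Cnot8 (26.5% against 22%, 0.0157), Carm1 (25.7% against 22.7%, 0.0147), Mrps22 (25.3%, 0.0147) and Rps3 (25.3%, 0.0147; all exact permutation), the 6 fusions with a low share of T before the edited A. Adjusted over all fusions GCATG passed for none. Rbfox2 (16.4% against 8.53%) and Ybx3 (8.56% against 8.18%) both had an exact permutation p of 0.0286 and an adjusted p of 0.121.

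Other splits of the same libraries were counted for each number of genes. The shares were not adjusted over the many splits run, of which about 1 in 20 falls under 0.05 by chance. For changed genes under knockdown, chance is argued against for Alyref (166 genes, highest other split 2, 1 of 35 splits as large, the smallest share possible). The same holds for Rps3 (6 and 6, 2 of 100). Its other split sets 4 of the 5 controls against all knockdown libraries and so repeats the real groups but for 1 library. For Rps2 (11 and 1, 1 of 100) and Hnrnpa1 (6 and 1, 1 of 100) no other split called as many. Their calls are the target and, besides it, gene models or pseudogenes, which can be copies that take reads from it. These 2 splits therefore say little about changes in other genes. For Ybx1 (4 and 20; 3 of 100), Mrps22 and Slbp (2 and 3 each; 4 of 100) few splits were as large, but another split called as many genes or more, and chance is left open. It cannot be excluded for Carm1 (1 and 1; 4 of 35), Cnot8 (2 and 4; 6 of 35), Hnrnpa2b1 (1 and 5; 15 of 100), Pcbp1 (1 and 1; 3 of 35), Ybx3 (1 and 3; 8 of 35), Elavl1 (1 and 2; 16 of 100), Igf2bp1 (1 and 2; 10 of 100), Magoh (1 and 3; 23 of 56), Ddx39a (1 and 3; 16 of 100), Rbfox2 (0 and 8; 100 of 100) and the 2 scrambled controls (0 and 11; 35 of 35). The highest splits for Cnot8 and for the scrambled controls set the 3 scrRNA01 libraries without a first digit of 2 against all others; with the digit as a block the real counts stayed at 2 and 0. A count of 1 gene, the target, is a weak measure of a knockdown whose target falls below every control.

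For changed genes in embryos with a fusion, chance is argued against for Ybx3 (1554 and 200, 1 of 35 splits, the smallest share possible). The same holds for Alyref (945 and 8, 1 of 100), Elavl1 (463 and 244, 1 of 84), Hnrnpa1 (246 and 5), Hnrnpa2b1 (56 and 4) and Ddx39a (10 and 1, a small count). For Magoh (7 and 12; 2 of 100), Igf2bp1 (5 and 12; 4 of 100), Slbp (4 and 4; 2 of 100) and Mrps22 (3 and 17; 2 of 100) another split called as many or more, and single libraries take the counts to 0, so chance is left open. It cannot be excluded for Ybx1 (2 and 2; 2 of 35), Rps3 (1 and 2; 9 of 100), Pcbp1 (1 and 5; 16 of 100), Rbfox2 (0 and 2), Carm1 (0 and 3), Rps2 (0 and 1) and Cnot8 (0 and 3). The larger splits for Ybx1 knockdown and for Igf2bp1 and Magoh embryos mix both groups and point to a structure of the libraries besides the groups.

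Genes edited were counted in either direction, because a split close to the reversed groups calls genes that a fusion edits less. Chance is argued against for Ybx3 (3185 genes, highest other split 2825), Alyref (2966 and 1769), Elavl1 (1769 and 1306), Rps2 (1027 and 632), Hnrnpa2b1 (483 and 331), Slbp (449 and 79), Magoh (418 and 217), Hnrnpa1 (266 and 0), Carm1 (244 and 110), Mrps22 (229 and 81) and Rps3 (72 and 28), each with 1 split as large (of 35 for Ybx3). It is left open for Ddx39a (18 and 14) and Pcbp1 (1 and 0), whose counts are small, for Cnot8 (28 and 40; 2 of 100) and Rbfox2 (35 and 432; 2 of 35), and cannot be excluded for Ybx1 (254 and 1177; 3 of 56) and Igf2bp1 (1461 and 2237; 13 of 100). In the highest split for Rbfox2 its library r001 stands with 3 of the free editor, and in that for Igf2bp1 libraries r401 and r402 stand with 2 of the free editor, which points to a structure of the libraries besides the groups.

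The planned count took genes edited more alone. For Carm1 (2 and 109; 15 of 100), Mrps22 (8 and 75; 14 of 100), Rps3 (1 and 23; 17 of 100), Magoh (2 and 217; 5 of 100), Slbp (6 and 79; 4 of 100) and Cnot8 (0 and 40; 100 of 100) its highest split is close to the reversed groups, so it decides nothing. All 8 genes of Mrps22 are mitochondrial, and mt-Co1 held 65 to 93 sites a library against 7 to 21 in the free editor. For the others it gave Ybx3 3183 and 1, Alyref 2947 and 1765, Elavl1 1693 and 1300, Rps2 1010 and 632, Hnrnpa2b1 376 and 327, Hnrnpa1 264 and 0, Ybx1 254 and 2 (1 of 56), Ddx39a 6 and 7 (2 of 100), Pcbp1 1 and 0, Igf2bp1 1460 and 2237 (13 of 100) and Rbfox2 35 and 432 (2 of 35).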
